A study of Homo sapiens with 6 samples.

How the data were processed

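RNA from human hepatic stellate cells obtained from a company was sequenced in 6 libraries. In 3 the cells carried a control short hairpin RNA (shRNA) and in 3 an shRNA against GIPC. In all 6 the cells had been starved of serum overnight and then treated with TGFβ for 2 hours. Libraries carry the numbers given in the labels, 3, 6 and 9 for the control group and 12, 15 and 18 for the GIPC group. Per the labels, libraries 3 and 6 were sequenced on lane 1, libraries 9 and 12 on lane 2, and libraries 15 and 18 on lane 3. The labels write GIPC without a number, and GIPC1 was taken as the target because its older symbol is GIPC.

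The authors deposited a table of whole-number counts of reads per gene, with Ensembl identifiers, symbols, coordinates and a length for each gene model. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.12 and counted with featureCounts on the human genome build GRCh37 (hg19). The version of featureCounts, the annotation release, the use of strand and the treatment of reads that map to several places are not given in the sources used here. Reads of a gene and of an antisense or overlapping partner therefore may not be separated. Counts of near-identical family members, such as the smooth muscle actins ACTA2 and ACTG2 or the IFIT, MX and OAS families, are uncertain to that extent. All coordinates are those of the deposited table on GRCh37.

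The table held 57773 genes, of which those of the Y chromosome, XIST and TSIX are not described. Total counts per library ranged from 43.1 to 55.5 M. A gene at 1 count per 1 M reads (CPM) therefore rested on over 40 reads, and the spread between libraries rather than counting error set the precision for most genes. No pair of libraries agreed within sampling noise: within groups the chi-square statistic per degree of freedom over genes with at least 10 counts in the pair was 4.07 to 177.5, so all 6 libraries were counted separately.

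Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 2 groups (minimum count 10, minimum total count 15), which left 19998 genes, library sizes were scaled with TMM factors, and the quasi-likelihood F test compared the GIPC group with the control group with no other covariate. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes and are given as mean ± SD over 3 libraries. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Principal components were taken from log2 CPM with a prior count of 2.

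The test, its covariates, 31 gene lists, the rule for the genes to be named and most alternatives were fixed before the data were examined. The rule named 17 genes outright. It then took the 10 largest rises and 10 largest falls among genes that passed the test, had a mean of at least 5 CPM and did not overlap between groups (leaving out pseudogenes, unnamed loci, small RNAs and genes of the Y chromosome). From each list it took up to 4 members with the smallest adjusted p, or the 2 with the highest CPM where no member passed. This gave 129 genes, not all of which are described here. Other members of lists are named only to complete a count or a description and were chosen after their values were seen. Each list was tested against all other tested genes with camera (limma 3.58.1, voom values, preset correlation between genes of 0.01), adjusted over the 31 lists. Camera was also run with a correlation estimated for each list. That form gave a higher p even where the estimate lay below the preset value. For the insulin-like growth factor axis the estimate was -0.0152, and the unadjusted camera p went from 0.0159 to 0.0582. A call lost in that form therefore is not by itself a sign of correlation between genes. The fry test, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, was an alternative. Counts of changed list members are given over all tested genes and adjusted over the list alone.

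Short sequence words were scored in 3′ untranslated regions (UTRs). For 13617 of the 14030 tested protein-coding genes (97.1%) the longest annotated 3′ UTR of at least 50 bases was taken from the transcript sequences of GENCODE release 29 by gene identifier, and none of its coordinates were used, since that release is on another genome build. Each of 16255 words of 7 bases found in at least 50 of these genes was scored by the standardised mean log2 fold change of the genes that hold it, after regression on UTR length, GC content and expression level. The lowest and highest scores of 999 permutations of genes within classes of UTR length gave family-wise p-values, of which 0.001 is the smallest possible. Sites in coding sequence or in longer UTRs than those annotated were not searched. The scan and its decision rule were set before its scores were seen.

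The alternatives were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom, no low-count filter, at least 1 CPM in 3 libraries, lane as a covariate, each library left out in turn, mitochondrial genes and the 10 genes with the most counts left out, an adjusted p under 0.01, and a test against a fold change of 1.2 (glmTreat). A smooth trend with gene model length taken out of each library, and counts and list tests among genes without the 2 lowest-scoring words, were added after the data had been seen. So were the same list tests among genes without any 6-base part of these words, and the 95% interval of a list median, taken from the ranked fold changes of its members.

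The procedures were tested on simulated data. In simulated counts for 3 against 3 libraries over 19718 genes, with 50 changed genes of each size, edgeR recovered 8% of genes changed 1.5-fold, 48% of those changed 2-fold, 86% of those changed 4-fold and 100% of those changed 8-fold. Of its calls 5.47% were false. DESeq2 recovered 22%, 66%, 88% and 98%, with 27.5% of its calls false. The share of false calls depends on how many genes change, and far fewer were planted than were called in the data. These shares therefore do not carry over to the calls in the data. With a fall planted in 1 list, camera called that list and 1 of the 30 others. Genes were drawn independently, and some other lists share members with the planted list. The simulation therefore does not measure false list calls among correlated genes. The word scan gave the planted word the lowest score in 10 of 10 trials.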

Results

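Gene expression was measured by RNA sequencing in human hepatic stellate cells, the collagen-producing pericytes of the liver sinusoid. Cells carrying a control shRNA (3 libraries) were compared with cells carrying an shRNA against GIPC (3 libraries), both after 2 hours of TGFβ. The comparison asks how genes of stellate cell activation and fibrosis depend on GIPC, a PDZ-domain adaptor protein that binds the tails of several receptors. Total counts were 54.7, 55.5 and 49.6 M in control libraries 3, 6 and 9. They were 50.6, 53.04 and 43.1 M in GIPC shRNA libraries 12, 15 and 18. No library without TGFβ was analysed here.

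GIPC1 mRNA fell 5.83-fold with the GIPC shRNA, from 80.1 ± 3.05 CPM in control cells to 13.7 ± 3.84 CPM (SD, n = 3 each). Of 25 contractile and activation genes 11 fell and 14 did not pass. Among those that fell was ACTA2, the smooth muscle actin that marks activated stellate cells (4.66-fold lower). IGFBP3, a secreted binding protein of insulin-like growth factors, fell 3.43-fold. CTGF, a matricellular growth factor induced by TGFβ, fell 2.14-fold, whereas TGFBI, another TGFβ-induced gene, rose from 1627 ± 74.7 to 3062 ± 209 CPM. Interferon-stimulated genes were 8 of the 10 largest rises among genes with a mean of at least 5 CPM. Collagens, integrins, cholesterol synthesis genes and unfolded protein response genes fell as groups in the main list test. So did the contractile and activation list. None of these 5 lists passed with an estimated correlation between genes (adjusted p = 0.336 to 0.413). Nor did any other of the 31 lists, so that form of the test does not set these apart.

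GIPC1 (ENSG00000123159, chromosome 19, 14588572 to 14606944) stood at 18.0, 10.5 and 12.7 CPM in GIPC libraries 12, 15 and 18. Its log2 fold change was -2.54 (SE 0.20, adjusted p = 4.15e-04 by edgeR's quasi-likelihood test). The paralogs GIPC2 and GIPC3 lay below 1 CPM in both groups and did not pass (adjusted p = 0.866 and 0.109). They stood at 0.780 ± 0.130 and 0.737 ± 0.158 CPM for GIPC2 and 0.818 ± 0.0838 and 0.448 ± 0.180 CPM for GIPC3. GIPC3 had a log2 fold change of -0.87 in the main fit and of -1.9 with lane as a covariate. Only a single library of each group, on a shared lane, carries the group term in the fit with lane. The GIPC family list did not pass (camera adjusted p = 0.0803). It did without control library 3 or GIPC library 15 (adjusted p = 0.0412 and 0.0478, and 0.389 and 0.406 with an estimated correlation). It also passed with no low-count filter (camera adjusted p = 0.0169, 0.181 with an estimated correlation) and by fry (adjusted p = 0.0013). Since this list of 3 genes holds the shRNA target, these calls largely restate the fall of GIPC1 and do not show a fall of the family. IGFBP3 (ENSG00000146674, chromosome 7, 45951949 to 45961473) went from 434.5 ± 59.7 to 127 ± 6.12 CPM (log2 fold change -1.78, SE 0.13, adjusted p = 3.10e-04).

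**Figure D1:**
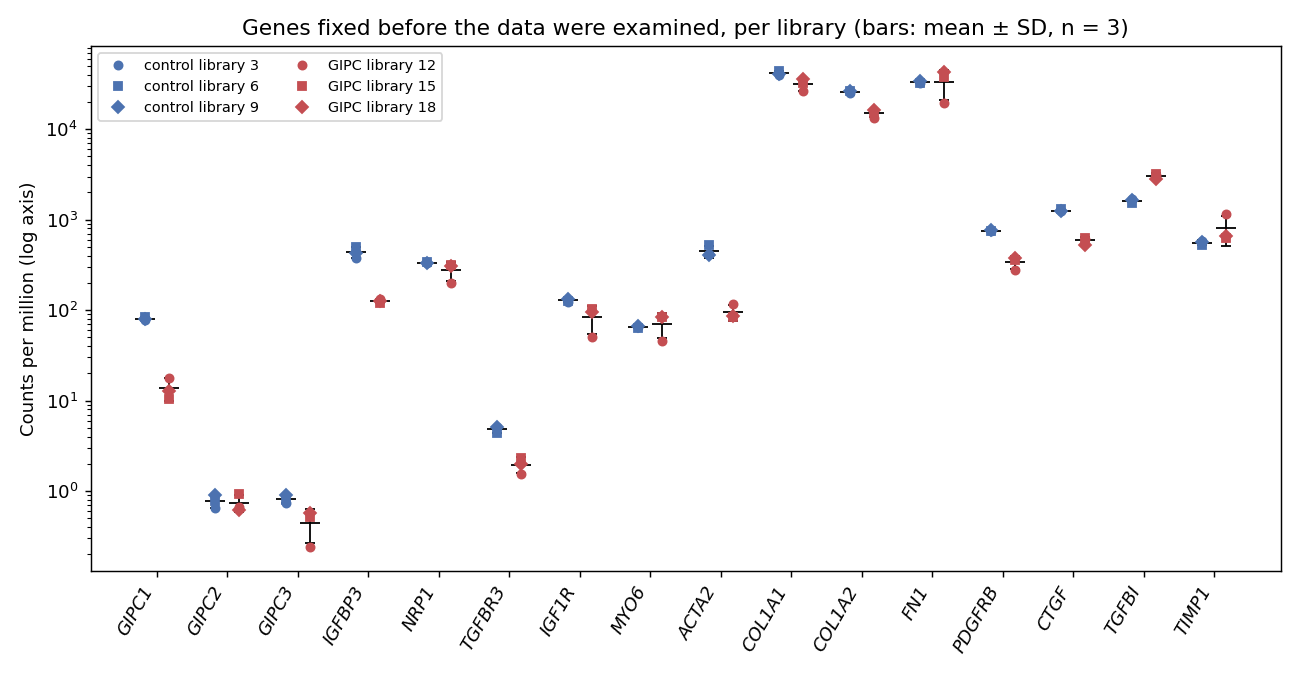
CPM on a log axis for 16 genes fixed before the data were examined, with each point a library (blue, control shRNA; red, GIPC shRNA) and each bar the mean ± SD of 3 libraries. GIPC1 fell from 80.1 to 13.7 CPM, and FN1 and TIMP1 show GIPC library 12 apart from libraries 15 and 18.

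In the list of activation and contractile genes 11 of 25 tested members fell and 0 rose, with 15 lower and 0 higher when adjusted over the list alone. The list passed (median log2 fold change -0.66, camera adjusted p = 1.58e-07, adjusted p = 0.336 with an estimated correlation). ACTA2 (ENSG00000107796, chromosome 10, 90694831 to 90751147) dropped from 446 ± 65.2 to 95.8 ± 19.0 CPM (adjusted p = 4.45e-04). LMOD1, an actin filament nucleator of smooth muscle, fell by 2.81 on the log2 scale. SRF, the transcription factor that drives actin genes, fell by 2.27, and CNN2, a calponin, fell by 1.15. PDGFRB, the receptor for platelet-derived growth factor on stellate cells, fell from 756.5 ± 17.8 to 340.1 ± 53.4 CPM (adjusted p = 0.00165). TAGLN and VIM, which encode transgelin and vimentin, had log2 fold changes of -0.58 and 0.14 and did not pass (adjusted p = 0.0857 and 0.457). The list median lay at -0.65, -0.78 and -0.78 relative to the control mean in GIPC libraries 12, 15 and 18.

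Among fibrillar and basement membrane collagens 7 of 22 fell and 2 rose, with 8 lower and 2 higher when adjusted over the list alone. The list passed (median -0.39, camera adjusted p = 0.00348, adjusted p = 0.413 with an estimated correlation). COL1A2, a chain of type I collagen, fell from 26080 ± 798 to 14950 ± 1456 CPM (log2 fold change -0.80, SE 0.12, adjusted p = 0.00379). COL1A1, the other chain (ENSG00000108821, chromosome 17, 48260650 to 48278993), stood at 41560 ± 2017 and 31540 ± 4934 CPM and did not pass (log2 fold change -0.40, adjusted p = 0.0885). Without GIPC library 12 it passed with a log2 fold change of -0.28 (adjusted p = 7.06e-04). The log2 fold change of COL1A1 was -0.64 with lane as a covariate. Only a single library of each group, on a shared lane, carries the group term in that fit. COL15A1, COL5A3 and COL8A2 had log2 fold changes of -2.73, -1.61 and -0.77. The 2 collagens that rose were COL10A1, which stayed below 1 CPM, and COL18A1 (log2 fold change 0.48). The collagen median was -0.68 in GIPC library 12 and -0.30 and -0.20 in libraries 15 and 18.

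Matrix glycoproteins, proteoglycans and crosslinking enzymes went both ways, with 13 of 36 lower and 5 higher (13 and 7 when adjusted over the list alone). The list did not pass (median -0.31, camera adjusted p = 0.0861). DCN, the proteoglycan decorin, fell from 1846 ± 87.0 to 509.5 ± 101 CPM. PLOD1, a collagen lysyl hydroxylase, fell by 1.36 and FBLN5, an elastic fibre protein, fell by 0.86 on the log2 scale. POSTN, the matrix protein periostin, rose from 110.0 ± 2.42 to 357 ± 31.3 CPM (adjusted p = 1.80e-04). FN1, which encodes fibronectin, averaged 32920 ± 856 CPM in control cells and 33140 ± 12270 CPM with the GIPC shRNA (adjusted p = 0.985). It stood at 19290 CPM in library 12 and at 37440 and 42690 CPM in libraries 15 and 18. Without library 12 it passed as higher (log2 fold change 0.28, adjusted p = 6.09e-04). With lane as a covariate its log2 fold change was -0.81, where control library 9 and GIPC library 12 carry the group term. Of matrix proteases and their inhibitors 7 of 28 rose and 3 fell (9 and 5 when adjusted over the list alone, camera adjusted p = 0.483). The plasminogen activators PLAU and PLAT rose by log2 fold changes of 0.96 and 0.80, and ADAMTS1 and the collagenolytic cathepsin CTSK fell by 1.38 and 1.45. TIMP1, an inhibitor of matrix metalloproteinases, was at 559 ± 30.5 and 810 ± 294 CPM (adjusted p = 0.146). It passed without library 12 (log2 fold change 0.20, adjusted p = 0.00412). With lane as a covariate its log2 fold change was 1.02, again resting on libraries 9 and 12.

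Early TGFβ target genes did not pass as a group: 8 of 32 rose and 6 fell (9 and 7 when adjusted over the list alone). Their median was 0.15 and the camera adjusted p 0.473. CTGF, now named CCN2, fell from 1263 ± 42.6 to 590 ± 50.8 CPM (adjusted p = 8.24e-04). ANGPTL4, an inhibitor of lipoprotein lipase, rose from 149 ± 26.5 to 625 ± 212 CPM (adjusted p = 0.00202). TGFBI rose by a log2 fold change of 0.91 (adjusted p = 0.00152). The inhibitory SMAD7, a direct TGFβ target, had a log2 fold change of 0.06 (adjusted p = 0.692). Among components of the TGFβ and BMP pathways 3 of 30 rose and 6 fell, also when adjusted over the list alone. The list did not pass (camera adjusted p = 0.218), but did as lower with lane as a covariate (median -0.428, adjusted p = 0.00664, and 0.485 with an estimated correlation), a fit in which control library 9 and GIPC library 12 carry the group term. GREM1, a secreted BMP antagonist, fell from 2390 ± 52.4 to 577 ± 81.8 CPM. TGFB2 fell by 1.22 on the log2 scale, and ID1, a target of BMP signalling, rose by 2.06. TGFBR3, the betaglycan co-receptor that binds GIPC, fell from 4.82 ± 0.426 to 1.96 ± 0.398 CPM (adjusted p = 0.00391). Of genes of quiescent stellate cells and retinoid storage 4 of 18 rose and 3 fell (5 and 3 when adjusted over the list alone). Their median was -0.04 (0.10 with scaling by total counts), their mean 0.04 and the camera adjusted p 0.909. NGFR, a neurotrophin receptor, and BAMBI, a TGFβ pseudoreceptor, rose 3.02-fold and 2.30-fold. ADAMTS13 and ECM1 rose 2.22-fold and 1.77-fold.

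Genes of the insulin-like growth factor axis fell in 8 of 20 cases and rose in 1, also when adjusted over the list alone (median -0.18, camera adjusted p = 0.0379, adjusted p = 0.336 with an estimated correlation). After IGFBP3 the smallest adjusted p-values belonged to the growth factor IGF2, which fell by 1.26, and STC2, an inhibitor of the IGFBP protease PAPPA, which fell by 0.90. The receptor IGF1R was at 128 ± 4.83 and 83.2 ± 28.3 CPM and did not pass (adjusted p = 0.114). Without library 12 it passed with a log2 fold change of -0.37 (adjusted p = 2.78e-05), and with the length trend taken out with -0.43 (adjusted p = 0.0142). With lane as a covariate its log2 fold change was -1.39, where control library 9 and GIPC library 12 carry the group term. Among binding partners of GIPC1 ACTN1 and TGFBR3 fell and 13 of 15 did not pass (2 lower when adjusted over the list alone, camera adjusted p = 0.109). The list passed as lower with lane as a covariate (median -0.392, adjusted p = 0.00376) and with no low-count filter (median -0.226, adjusted p = 0.0412), but in neither with an estimated correlation (adjusted p = 0.442 and 0.407). The semaphorin and VEGF co-receptor NRP1 was at 336 ± 7.62 and 275 ± 67.9 CPM and the endocytic motor MYO6 at 64.9 ± 1.36 and 70.9 ± 21.8 CPM (adjusted p = 0.308 and 0.724). With lane as a covariate NRP1 had a log2 fold change of -0.77. In that fit only control library 9 and GIPC library 12 carry the group term. NRP1 stood at 197 CPM in library 12 and at 318 and 311 CPM in libraries 15 and 18. MYO6 stood at 45.7 CPM in library 12. Without that library it passed as higher (log2 fold change 0.36, adjusted p = 8.48e-06). With lane as a covariate its log2 fold change was -0.54, from the same fit resting on libraries 9 and 12. In the list of growth factor, guidance and vasoactive signalling 14 of 37 fell and 3 rose (15 and 4 when adjusted over the list alone, camera adjusted p = 0.00196, adjusted p = 0.413 with an estimated correlation). PTGS1, which encodes cyclooxygenase 1, and the guidance ligand SEMA3A fell 2.42-fold and 2.92-fold. PDGFB, a growth factor for stellate cells, rose 1.97-fold.

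Integrins and focal adhesion genes fell in 13 of 28 cases and rose in 2 (15 and 2 when adjusted over the list alone, camera adjusted p = 3.41e-04, adjusted p = 0.336 with an estimated correlation). ITGB1, the shared β1 chain of collagen and fibronectin receptors, dropped from 3184 ± 37.8 to 659 ± 107 CPM. FERMT2, an integrin activator, the actin crosslinker FLNA and the collagen receptor chain ITGA1 had log2 fold changes of -2.28, -1.06 and -1.74. Target genes of YAP and TAZ fell in 9 of 24 cases and rose in 1, also when adjusted over the list alone (camera adjusted p = 0.00119, adjusted p = 0.413 with an estimated correlation). AJUBA, CYR61, F3 and AMOTL2 had log2 fold changes of -1.90, -1.76, -1.73 and -1.52. The list median was -1.06 in library 12 against -0.18 and -0.25 in libraries 15 and 18. Of inflammatory chemokines and cytokines 10 of 29 fell and 3 rose (11 and 4 when adjusted over the list alone, camera adjusted p = 0.0159, adjusted p = 0.454 with an estimated correlation). That call was lost without control library 9 or GIPC library 15 (adjusted p = 0.0622 and 0.0738). It was also lost with lane as a covariate (adjusted p = 0.163), and the list median was 0.0316 in library 12 against -0.521 and -0.364 in libraries 15 and 18. The adhesion molecule VCAM1, the macrophage growth factor CSF1 and the chemokine CXCL12 had log2 fold changes of -2.64, -1.42 and -1.32, and the interferon-induced chemokine CXCL10 rose by a log2 fold change of 1.44.

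The type I interferon response rose in 23 of 27 tested genes and fell in 0 (25 and 0 when adjusted over the list alone). The median log2 fold change was 2.06 (camera adjusted p = 5.60e-14, adjusted p = 0.336 with an estimated correlation of 0.633 between its genes). MX1, an antiviral GTPase, rose from 8.51 ± 1.49 to 75.02 ± 28.5 CPM, and IFI44L from 4.86 ± 0.947 to 34.7 ± 11.7 CPM. IFI44 rose from 6.23 ± 0.515 to 25.9 ± 6.72 CPM and OAS2, a sensor of double-stranded RNA, from 0.972 ± 0.0178 to 7.70 ± 3.22 CPM (adjusted p = 7.47e-04 to 0.00124). The list median was 2.34, 2.29 and 1.44 in libraries 12, 15 and 18. Among genes with a mean of at least 5 CPM and no overlap between groups, the 10 largest rises were BST2, MX1, HERC6, MX2, IFIT1, IFI44L, ITGB8, IFI6, CILP and IFITM1, with log2 fold changes of 3.17 to 2.37. All but the integrin ITGB8 and the cartilage matrix gene CILP are known interferon-stimulated genes. Among the 10 largest falls by the same rule were AHNAK, DAP, CD4, KIAA1199, SLC6A9, FOXF2, TMEM47, TNNT2 and SLC7A2, with log2 fold changes of -4.20 to -2.99. AHNAK, a giant scaffold protein beneath the plasma membrane, went from 2076 ± 181.5 to 113 ± 55.1 CPM (adjusted p = 8.12e-04).

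Metabolic and stress genes fell in 4 lists. Cholesterol biosynthesis was lower in 12 of 25 genes and higher in 0 (15 and 1 when adjusted over the list alone, camera adjusted p = 1.74e-06, adjusted p = 0.336 with an estimated correlation). SREBF2, the transcription factor of the pathway, and INSIG1, its sterol-dependent anchor, had log2 fold changes of -2.48 and -2.41. The unfolded protein response and amino acid stress list was lower in 13 of 26 genes and higher in 0 (17 and 0 when adjusted over the list alone, camera adjusted p = 9.81e-07, adjusted p = 0.336 with an estimated correlation). The serine synthesis enzyme PSAT1, HERPUD1, which acts in degradation of proteins from the endoplasmic reticulum, TRIB3 and the asparagine synthetase ASNS fell 3.01-fold, 3.10-fold, 3.54-fold and 2.61-fold. Hypoxia and glycolysis genes fell in 10 of 24 cases and rose in 2 (11 and 4 when adjusted over the list alone, camera adjusted p = 0.00927, adjusted p = 0.336 with an estimated correlation). The glucose transporter SLC2A1 and the glycolytic enzymes ALDOC and PFKP fell 3.08-fold, 3.57-fold and 2.02-fold, and the enolase ENO2 rose 2.17-fold. Oxidative stress and NRF2 genes fell in 10 of 26 cases and rose in 1 (12 and 1 when adjusted over the list alone, camera adjusted p = 0.00196, adjusted p = 0.454 with an estimated correlation). SOD2, GCLM and ME1 had log2 fold changes of -1.65, -1.26 and -0.93. The median of the hypoxia list was -0.09 in library 12 against -0.46 and -0.52 in libraries 15 and 18. That of the oxidative stress list was -0.19 against -0.49 and -0.44. With lane as a covariate both calls were lost (medians -0.0497 and -0.209, adjusted p = 0.487 and 0.588).

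**Figure D2:**
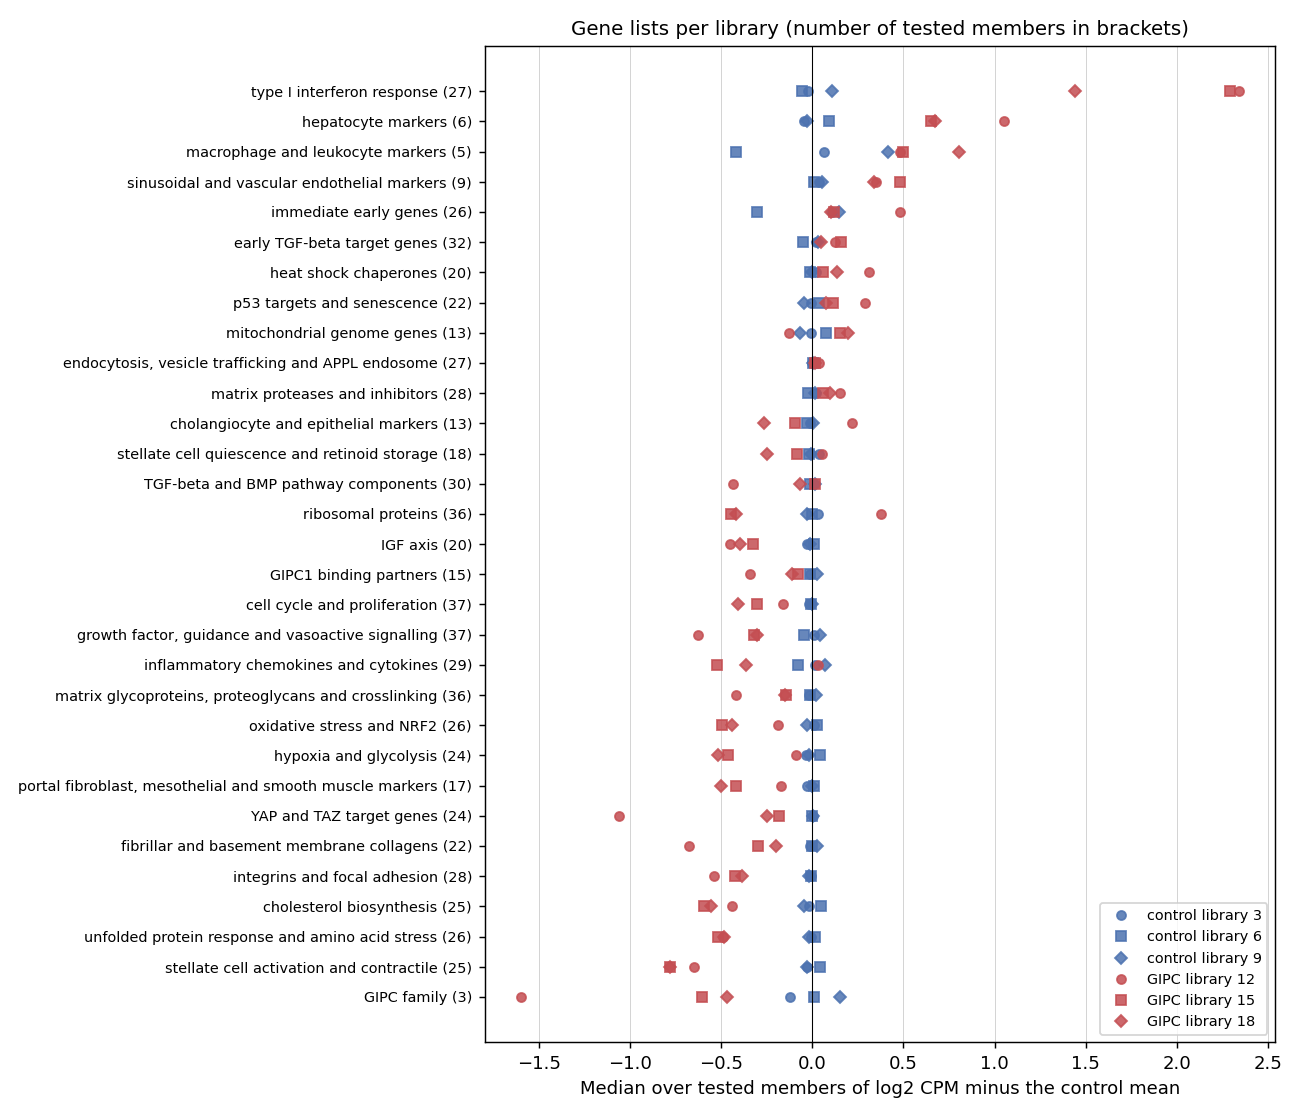
Median over the tested members of each gene list of log2 CPM minus the mean of the control libraries, with each point a library (blue, control shRNA; red, GIPC shRNA) and the number of tested members in brackets. The interferon list stood at 1.44 to 2.34 in the GIPC libraries, and the ribosomal protein list shows library 12 on the other side of 0 from libraries 15 and 18.

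Of hepatocyte markers 6 of 24 were tested, and ALB, which encodes albumin, averaged 0 CPM in control and 0.0257 CPM in GIPC libraries, here scaled by total counts. In all 2 members passed as higher, among them CYP2E1, a cytochrome P450 enzyme, from 0.5295 ± 0.0915 to 1.09 ± 0.246 CPM. Adjusted over the list alone 3 members were higher, and the list passed with a median of 0.77 (camera adjusted p = 0.0473, adjusted p = 0.336 with an estimated correlation). That call was lost without control library 9, GIPC library 12 or GIPC library 18 (adjusted p = 0.0518, 0.114 and 0.0711), with scaling by total counts (0.0832) and with lane as a covariate (0.414). Sinusoidal and vascular endothelial markers did not pass (9 tested, 1 higher and 1 lower, 2 and 1 when adjusted over the list alone, camera adjusted p = 0.415). The angiopoietin receptor TEK fell from 23.6 ± 0.973 to 12.0 ± 3.60 CPM, and VWF rose from 1.42 ± 0.157 to 2.45 ± 0.369 CPM. Macrophage and leukocyte markers did not pass (5 of 26 tested, 1 higher, 1 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.483). The member that passed, CD79A, was at 0.120 ± 0.0469 and 0.336 ± 0.114 CPM. The calls of CYP2E1, TEK, VWF and CD79A were lost without control library 3, 6 or 9 (adjusted p = 0.0701 to 0.174). Cholangiocyte and epithelial markers did not pass (13 tested, 1 higher and 1 lower, also when adjusted over the list alone, camera adjusted p = 0.909). The tight junction gene CLDN4 rose from 25.2 ± 6.07 to 81.8 ± 33.2 CPM and the mucin MUC1 fell from 2.69 ± 0.0942 to 1.30 ± 0.215 CPM. Markers of portal fibroblasts, mesothelium and smooth muscle did not pass (17 tested, 3 higher and 4 lower, 3 and 5 when adjusted over the list alone, camera adjusted p = 0.0803), but did without control library 3 or GIPC library 12 (adjusted p = 0.0412 and 0.0216, and 0.464 and 0.38 with an estimated correlation). RGS5 and DES had log2 fold changes of -1.53 and -1.14, and FBLN2 and MFAP4 of 0.84 and 0.61.

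Over all genes 4261 of 19998 (21.3%) changed, 1937 higher and 2324 lower, and 1602 of these changed at least 2-fold (628 higher and 974 lower). The groups did not overlap in 9186 genes (45.9%, against 10% by chance for 3 against 3 libraries). GIPC library 12 stood apart from libraries 15 and 18: its mean absolute log2 difference from them was 0.522 and 0.541 (0.208 between 15 and 18, and 0.193 to 0.2095 between control libraries). It differed from them along both principal components. It lay at 74.14 against 31.03 and 25.29 on the first (59.5% of variance), which separated the groups, and at -45.87 against 37.23 and 38.21 on the next (24.5%). Without library 12 the count was 10017, without GIPC library 15 it was 2762, and without control library 3, 6 or 9 it was 1791, 1827 and 1806. Scaling by total counts moved all log2 fold changes up by a median of 0.141 and turned the split of calls to 3324 higher and 1758 lower. The split also went with gene model length: 347 genes were higher and 181 lower in the shortest 20% of 14030 protein-coding genes, against 196 and 462 in the longest 20%. Log2 fold changes fell with length (Spearman rho -0.223 across these genes, which are not independent replicates), and less so without library 12 (rho -0.0223).

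**Figure D3:**
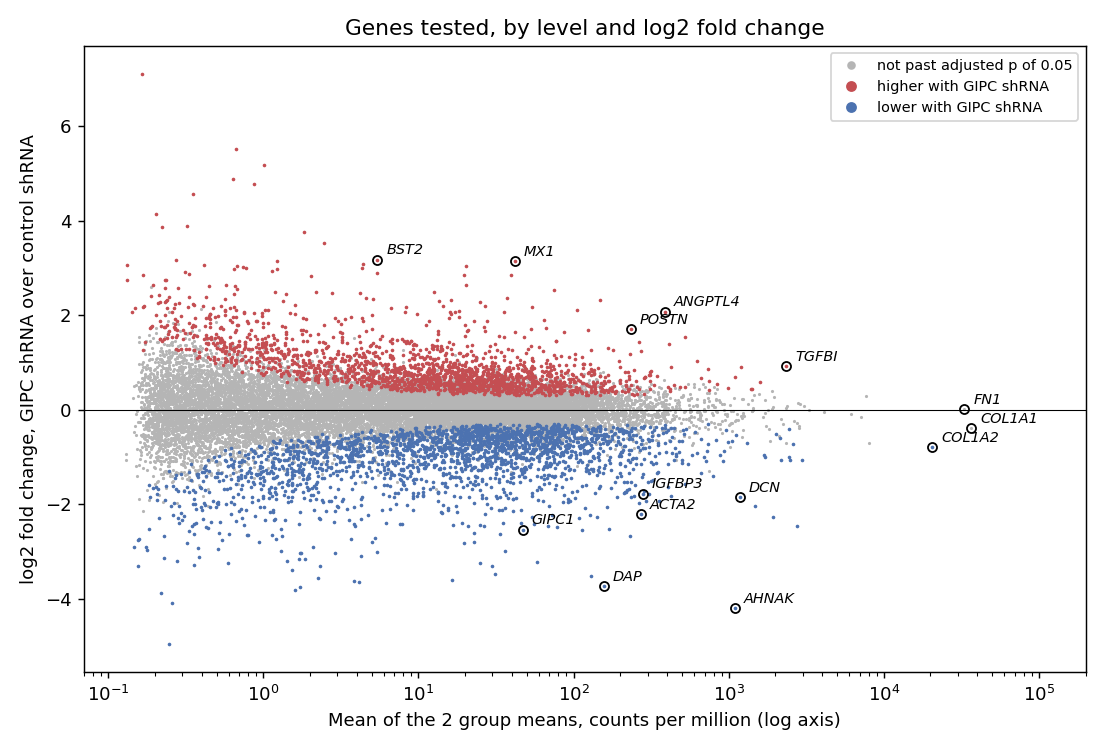
Log2 fold change (GIPC shRNA over control shRNA) against the mean of both group means in CPM on a log axis, with each point a tested gene coloured by whether it passed an adjusted p of 0.05. AHNAK (-4.20) and DAP (-3.74) lay lowest and the interferon genes BST2 (3.17) and MX1 (3.14) highest among the labelled genes.

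The genes that fell were rich in a short sequence of the 3′ UTR. Of 16255 words of 7 bases, ATTTGCC had the lowest score (-18.7) and TTTGCCA, which overlaps it by 6 bases, the next lowest (-15.1). The lowest score of the permutations was -5.35 (family-wise permutation p = 0.001, the smallest they can give). Either word was present in 25.5% of the 13617 searched genes, in 47.9% of those that fell, in 58.3% of those that fell at least 4-fold and in 13.2% of those that rose. Among the 3470 genes with a word 26.6% fell, against 9.9% of the 10147 genes without one. Unlike the scores, these shares were not adjusted for UTR length, GC content or expression level. The gaps between them therefore do not measure the effect of a word alone. Of the genes named above as lower, AHNAK, DAP, CD4, FOXF2, TMEM47, SLC7A2, CTGF, COL1A2, SRF, CNN2, GREM1, TGFB2, ADAMTS1, PTGS1, SEMA3A, ITGB1, FERMT2, ITGA1, CXCL12, AJUBA, SREBF2, INSIG1, SLC2A1, PFKP, SOD2, GCLM, TEK and RGS5 held a word. GIPC1, IGFBP3, ACTA2, PDGFRB, LMOD1, TGFBR3, DCN, COL15A1, COL5A3, COL8A2, IGF2, STC2, VCAM1, CSF1, CYR61, F3, AMOTL2, ACTN1, FLNA, PLOD1, FBLN5, CTSK, PSAT1, ASNS, HERPUD1, TRIB3, ALDOC, ME1, KIAA1199, SLC6A9, TNNT2, MUC1 and DES held none in the annotated 3′ UTR. In a test chosen after the data were seen, 5 lists lost their call among genes without a word. These were the insulin-like growth factor axis (median -0.176, adjusted p = 0.128), growth factor signalling (-0.156, 0.128), YAP and TAZ targets (-0.0719, 0.0805), hypoxia and glycolysis (-0.00821, 0.521) and hepatocyte markers (0.774, 0.103, with no word in any of the 6 members). A word was held by 4 of the 8 fallen members of the first of these lists, 9 of 14 of the next, 6 of 9 YAP and TAZ targets and 7 of 10 hypoxia genes. The insulin-like growth factor median hardly moved, from -0.185 with 20 members to -0.176 with 13. Its lost call therefore does not show a smaller fall without the words, since fewer members were tested. Among the 5461 genes without any 6-base part of the words, where the lists have fewer members, 4 more lists lost their call in a test also chosen after the data were seen. These were cholesterol biosynthesis (median 0.0318, adjusted p = 0.369), collagens (-0.185, 0.0683), inflammatory chemokines and cytokines (-0.0218, 0.117) and oxidative stress (-0.291, 0.0683). All 6 early TGFβ target genes that fell held a word, and 1 of the 8 that rose did.

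**Figure D4:**
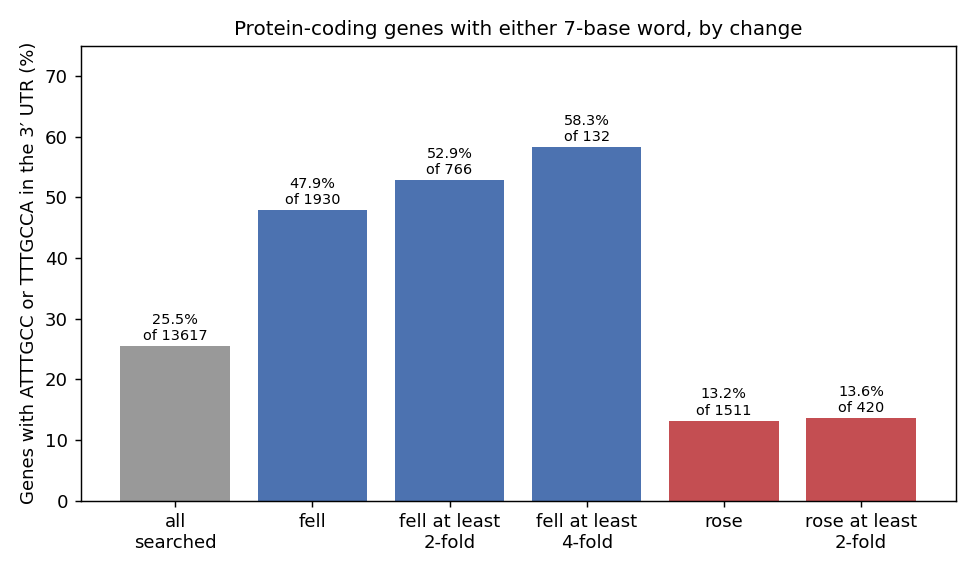
Percent of searched protein-coding genes whose longest annotated 3′ UTR held ATTTGCC or TTTGCCA, for all searched genes (grey) and for those that fell (blue) or rose (red) with the GIPC shRNA, with the percent and the number of genes above each bar. The share was 25.5% in all searched genes, 58.3% in genes that fell at least 4-fold and 13.2% in genes that rose. Shares are not adjusted for UTR length.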

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

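The tests among genes without either 3′ UTR word and with the gene length trend taken out were chosen only after the result was seen. The count of 4261 changed genes stayed within 1.5 times under the other scalings, tools and filters (4106 to 5320), and calls shared with it had the same sign under each alternative. It was 1757 (628 higher, 1129 lower) at an adjusted p under 0.01 and 2563 (1025 and 1538) against a fold change of 1.2, which are stricter by construction. With lane as a covariate it was 11221 (5525 and 5696, with 3946 at least 2-fold), a fit in which the group term rests on control library 9 and GIPC library 12. Total-count scaling gave 3324 higher genes. Leaving out 1 library gave 1791 to 10017 genes (613 to 4826 higher, 1178 to 5191 lower), fewest without control library 3 and most without GIPC library 12. Among genes without either word it was 2318 (1006 lower, 724 at least 2-fold), from fewer genes, and with the length trend taken out it was 5322. GIPC1 kept its call in the 16 alternatives that gave it a fold change (log2 -2.79 to -2.14). Of 119 named genes that passed, 17 lost their call without some single library (adjusted p = 0.0501 to 0.186), among them PAPPA2, DDB2, FOSL2, JUNB, DUSP6, OPTN, RAB11A, DAB2, HSP90AA1, HSPH1, DNAJB1, MT-ND6, CYP2E1, TEK, VWF and CD79A. Among the 119, DESeq2 lost 1 call, total counts, limma-voom and no filter lost 2 each, and lane as a covariate lost some. With lane as a covariate MYO6 (-0.54), FN1 (-0.81), RPL3 (0.176) and the ribosomal protein list (median 0.398) reversed. Of the gene lists 14 passed, against 13 to 17 without single libraries, 13 with total counts or lane, 15 with the length trend taken out, 21 with no filter, 10 among genes without a word, 19 by fry and 0 with an estimated correlation, where the collagens had an adjusted p of 0.413 (median -0.394) and the activation list 0.336 (median -0.664). The matrix glycoprotein list passed with no filter (median -0.318), with lane (-0.504) and by fry (-0.309), GIPC1 partners (-0.392) and TGFβ and BMP components (-0.428) passed with lane, and the early TGFβ targets passed as higher among genes without a word (median 0.241). No list passed with an estimated correlation under any of these settings where both were run (adjusted p of at least 0.143), the matrix glycoproteins (0.181 with no filter, 0.442 with lane) and early TGFβ targets (0.426) included. Other causes were not tested. Genes under the low-count filter were not tested in the main fit, most hepatocyte and leukocyte markers among them.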

Other observations

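The tests of gene length as the whole of a difference, of 3′ UTR composition, of a short RNA from either hairpin strand, of 6-base parts of the words, and with the length trend taken out were chosen only after the result was seen, as was the interval of a median. Cell cycle genes fell in 12 of 37 cases and rose in 1 (12 and 3 when adjusted over the list alone, camera adjusted p = 0.00778, adjusted p = 0.413 with an estimated correlation and 0.588 with lane as a covariate). The mitotic kinesin KIF23, CDC20, which activates the anaphase-promoting complex, and the topoisomerase TOP2A fell 2.68-fold, 2.85-fold and 2.54-fold. The G1 cyclin CCND1 rose from 844 ± 25.7 to 1574 ± 183 CPM. Targets of p53 and senescence genes rose in 5 of 22 cases and fell in 1 (5 and 2 when adjusted over the list alone, camera adjusted p = 0.0856). The antiproliferative BTG2, the sestrin SESN1 and the kinase PLK3 rose 2.62-fold, 2.07-fold and 1.84-fold. Immediate early genes rose in 4 of 26 cases and fell in 2, also when adjusted over the list alone (camera adjusted p = 0.0861). The list passed without control library 3 or 9 or GIPC library 15 (adjusted p = 0.0368, 0.0314 and 0.0489, and 0.693, 0.62 and 0.698 with an estimated correlation). DUSP4, a phosphatase of MAP kinases, rose from 7.51 ± 1.39 to 29.2 ± 2.56 CPM.

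Genes of endocytosis, vesicle trafficking and the APPL endosome, the compartment where GIPC1 acts, fell in 4 of 27 cases and rose in 1, also when adjusted over the list alone (camera adjusted p = 0.909), and RAB5B, an early endosome GTPase, fell by 0.61 on the log2 scale. Heat shock chaperones rose in 2 of 20 cases and fell in 2 (1 and 2 when adjusted over the list alone, camera adjusted p = 0.483), and BAG3, a co-chaperone, fell by 0.80. Of 36 ribosomal protein genes 0 passed by edgeR, also when adjusted over the list alone (camera adjusted p = 0.109), 0 had an unadjusted p under 0.05, and 0 passed by DESeq2 or limma-voom. RPL4 was at 1203 ± 18.8 and 1012 ± 249 CPM and RPL3 at 1135 ± 39.8 and 927 ± 292 CPM. The median of the list was 0.375 in GIPC library 12 and -0.444 and -0.418 in libraries 15 and 18. The estimated correlation between its genes was 0.991 (adjusted p = 0.824 with it). The list passed as lower without library 12 (median -0.431, adjusted p = 9.26e-18), with the length trend taken out (-0.172, 0.0231) and with no filter (-0.129, 0.0168), but in none of these with an estimated correlation (adjusted p = 0.324, 0.762 and 0.759). With lane as a covariate the list median was 0.398, higher rather than lower, in a fit resting on control library 9 and GIPC library 12. RPL4 and RPL3 passed as lower without library 12 (log2 fold changes -0.47 and -0.58). Of 13 mitochondrial genome genes MT-ND6 rose, also when adjusted over the list alone (camera adjusted p = 0.483). It lost its call without control library 3, 6 or 9 or GIPC library 15 (adjusted p = 0.0501 to 0.106), and the list passed as higher without GIPC library 12 (adjusted p = 0.0413, 0.7 with an estimated correlation).

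The genes that fell were rich in 2 words of the 3′ UTR, and a short RNA made from the hairpin that pairs with them may account for part of the fall. UTR length and GC content, as modelled, had been regressed out before scoring, so the score of -18.7 for ATTTGCC stood after them. The reverse complements of the words scored 1.9 and 2.15. They share GC content with the words but swap A with T and G with C, so single-strand base composition stays untested. A short RNA from the hairpin, whichever strand carries it, remains a candidate explanation: ATTTGCC had the lowest score of all words in each GIPC library (-15.52, -20.3 and -19.8 in libraries 12, 15 and 18) and -0.67 to 0.67 in control libraries (permutation p = 0.01 in each GIPC library, the smallest they can give). The word was picked from these same libraries and each was scored against the same controls, so the scores are not independent. A group-level cause other than the hairpin could give the same contrast with control libraries. Whether such an RNA is the intended guide stays open. The scan passed (family-wise permutation p = 0.001, the smallest possible). However, 0 of 13 GIPC1 transcripts held either word, and the rule fixed beforehand asked for the strongest word in them. They held ATTTGC and low-scoring words such as TTTGCCT (-8.76) and TGCCAAA (-8.28), both of these with a family-wise permutation p = 0.001. They also held high-scoring words such as TGGTGGT (4.06) and CTACCTC (3.98). No chance rate of such matches was computed, so they do not decide the question. The shRNA sequence is not given in the sources used here. A response to the loss of GIPC1 also stays open for the 1006 lower genes without a word and for the others, and was not tested.

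The activation and contractile list fell, with 11 of 25 members lower. Its 19 members without a word had a median log2 fold change of -0.664 (95% interval -1.09 to -0.223), 8 of them fell, and the list passed among genes without a word (camera adjusted p = 6.89e-07, adjusted p = 0.387 with an estimated correlation). Its 12 members without any 6-base part of the words had a median of -0.368 (-2.07 to 0.143), and 3 of them fell (ACTA2, ACTG2 and LMOD1, camera adjusted p = 9.85e-05, adjusted p = 0.528 with an estimated correlation). The rule fixed beforehand, on the median and camera p without a word, went against direct matches of the words as the whole fall. A bound on the interval, added after the data were seen, was not met. For the 19 members without a word the values argue against direct matches in annotated 3′ UTRs as the whole, since their interval is negative throughout. That interval treats the members as independent, while their estimated correlation was 0.125. It measures the spread between genes and not between libraries. The 6 members with a word had a median of -0.778, and 3 fell. A part played by the words stays open, as do matches of 6-base parts, where the interval is wide, and sites not searched. An indirect path through SRF, which drives many of these genes, held a word and fell, could add to the fall. A response to the loss of GIPC1 could as well, and neither was tested.

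GIPC library 12 differed from libraries 15 and 18 by more than any control library did from the others. The tables argue against lane 2, since control library 9 of that lane had 1.99% of the excess difference of library 12. The difference did not follow the GIPC shRNA effect (mean Spearman rho -0.0348 across 19998 genes). That cannot exclude a weaker knockdown, since the trend with gene length described next was not taken out first. GIPC1 itself stood at 18.0 CPM in library 12 and at 10.5 and 12.7 CPM in libraries 15 and 18. A trend with gene length is present and may be technical: the difference fell with gene model length (Spearman rho -0.563 across 14030 protein-coding genes, which are not independent replicates), from a median of 0.495 in the shortest 20% of genes to -0.512 in the longest 20%. The smooth trend as taken out is not the whole, since 83.2% of the excess was left without it. Some trend remained: libraries 15 and 18 minus library 12 had rho with length of 0.552 and 0.551 before and 0.126 and 0.131 after. A technical cause tied to length in another way therefore stays open, and no biological explanation was tested.

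Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one, with 4261 by edgeR against 0 for the highest of the other splits. The other splits gave up to 660 genes at an unadjusted p under 0.05, against 7172 for the real split, and up to 1 by DESeq2, against 5320. With 10 splits the share cannot go under 0.05. Each of the other splits also mixes control and GIPC libraries in both arms. A large group difference then widens the spread within arms, so few calls follow. The splits cannot tell the shRNA from another difference between the groups.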
